A study of Homo sapiens with 8 samples.

How the data were processed

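Total RNA from T47D cells, a hormone-receptor-positive human breast cancer line of luminal type, was sequenced in 8 libraries. Per the labels, the cells carried a control plasmid or a plasmid for HA-tagged GATA3 in its wild-type form or in 1 of the truncated forms TR1 and TR2, with 2 libraries for each of the 4 groups. The labels name a strand-specific library kit. They do not say whether replicates came from separate cultures, so p-values here measure only the spread between these samples. TopHat, HTSeq and the genome build hg38 are named in the submitters' processing notes, without versions. The annotation, the strand setting of the counting and the way the library factors were computed are not stated.

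The authors deposited log2(normalized count + 1) values for 28859 gene symbols in the 8 libraries. Within each library, the values turned back to the linear scale were whole multiples of a single step, which gave the read count behind each value. With this step, 100% of values fell within 0.01 of a whole read, and the largest deviation was 0.00125 reads. The libraries held between 13292861 and 19572394 reads on genes, and 1146 genes had 0 reads in all 8. Among the deposited gene names, 15 had been turned into dates, and 12 of them passed the filter below. They were tested under the names as deposited and none is named here. By symbol, 19992 genes matched GENCODE release 29, from which coordinates (GRCh38, 1-based), transcript lengths and GC contents were taken.

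Genes with a normalized count of at least 10 in at least 2 libraries were kept, which left 14881 genes, and 12875 of them (86.5%) had an annotated transcript. The 6 pairwise comparisons of the 4 groups were tested with limma 3.58.1 in R 4.3.3, by lmFit, contrasts and eBayes with a trend, on the deposited log2 values. All 8 libraries entered 1 fit with group as the only term, which left 4 residual degrees of freedom and 4.69 prior degrees of freedom. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Fold changes are on the log2(value + 1) scale and understate the change of genes with low counts. Values are given as mean normalized counts ± SD (n = 2 libraries), and log2 fold changes with their standard error (SE).

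Where a group had 0 reads, a fold is given as a lower bound against a floor of 3 reads per library. Where it had 1 to 3 reads, the ratio of normalized reads is given with its exact 95% binomial counting interval. Intervals and floors cover counting error only.

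Lists of genes were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted by the Benjamini-Hochberg method over the lists within a comparison. There were 22 lists, drawn up from general knowledge of luminal breast cancer programs, markers of other cell types and RNA quality, and 5 more were written after the genes had been looked at. The 5 later lists were adjusted among themselves only, apart from the 22. The tests, the 22 lists, most of the alternatives and the rule for naming genes were fixed before the data were examined. By this rule, each comparison selects GATA3, then the 8 largest rises and the 8 largest falls among genes past the threshold whose libraries did not overlap, leaving out clone-like names. It also selects up to 4 members per list past the threshold with the largest fold change, and the markers CDH1, VIM, FN1, ZEB1, SNAI2, ESR1, PGR, FOXA1 and KRT8 whatever their values. GATA3 and the markers other than SNAI2 are given for every comparison, but only part of the other genes selected is given, chosen after their values and alternatives were seen and mostly for calls that held. SNAI2 was not analysed here, because its symbol was not matched in the table, and ZEB1 did not pass the filter.

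Correlations of fold changes across genes were set beside 100 simulations of unchanged groups that share a control. The simulated values were the same for every pair of comparisons, although the groups differ in their spread. Comparisons against a shared control share its chance values, and the controls could not be split, because each part would hold 1 library. Genes are not independent replicates, so no p-value is given for these correlations. The pipeline was tested on simulated data of 14635 genes with 200 changed genes in TR1 against the control. It called 176 genes, of which 11 were unchanged, and recovered 68% of the 2-fold and 97% of the 4-fold changes. In a simulation of wild type against the control with no change, it called 0. The simulated groups all had the same spread at a given mean count and no length or GC trend. These results therefore do not show how the pipeline performs where groups differ in spread, as they do here.

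The alternatives were a prior variance with no trend, robust empirical Bayes, no filter, a filter at a normalized count of 100, median centring, quantile normalization and a pseudocount of 10. The others were a fit of only the groups compared, the replicate number as a block, adjustment over all 6 comparisons, voom weights on the recovered reads, and leaving out each library in turn. For lists, camera with an estimated correlation and fry were also run. Camera compares a list with the other genes, whereas fry tests whether its members move one way on balance and compares them with no other genes. Removal of a trend in transcript length and GC content with splines of 5 degrees of freedom, and a fit limited to annotated genes, were chosen after seeing the data. Where 1 library of a group is left out, the other is assumed to vary like the other groups.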

Results

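The data were whole-transcriptome RNA-seq profiles of T47D cells, an established luminal breast cancer line. GATA3 is a transcription factor of luminal breast epithelium. The 8 libraries formed 4 groups of 2, with a control plasmid, wild-type GATA3, truncated TR1 or truncated TR2. The control libraries held 15105536 and 13292861 reads on genes, the wild-type libraries 16620794 and 14115695, the TR1 libraries 16970383 and 19572394, and the TR2 libraries 18154045 and 17377907. Mitochondrially encoded genes took between 7.11% and 8.50% of the normalized counts of each library. Pearson's r across genes was 0.98589 between the TR1 libraries and between 0.992 and 0.994 within the other pairs. Between a TR1 and a TR2 library it was higher than within TR1, from 0.98636 to 0.98795. The SD of the log2 difference between replicates, over 10124 genes with an annotated transcript and higher counts, was 0.386 for TR1, against 0.173 for the control, 0.123 for wild type and 0.135 for TR2.

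GATA3 itself (ENSG00000107485, chromosome 10, 8045378 to 8075203) was counted at 13730 and 12680 in the control libraries and at 13560 and 13830 with wild type. It was counted at 9506 and 8638 with TR1 and at 10240 and 10590 with TR2. Wild-type libraries did not differ detectably from the control (log2 fold change 0.05 ± 0.07 SE, limma adjusted p = 0.743). GATA3 was lower with TR1 than with the control (-0.54 ± 0.07, adjusted p = 0.00149) and than with wild type (-0.60, adjusted p = 0.000539). With TR2 it was lower than with wild type (-0.40, adjusted p = 0.0104), and its difference from the control did not pass the threshold (-0.34, adjusted p = 0.0578). The call of TR2 against wild type was lost without wild-type replicate 1 (adjusted p = 0.0964), wild-type replicate 2 (0.122), TR2 replicate 1 (0.117) or TR2 replicate 2 (0.0782), and with no trend in the prior variance (0.0701). The TR2 difference from the control passed without TR1 replicate 1 (adjusted p = 0.000517) or TR1 replicate 2 (0.000463), with robust empirical Bayes (0.0426), quantile normalization (0.0324), only these groups (0.00269), adjustment over all 6 comparisons (0.021) or the length and GC trend removed (0.0364), and its adjusted p lay between 0.000463 and 0.444 over all alternatives. The counts do not separate endogenous transcripts from those of the plasmids.

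**Figure D1:**
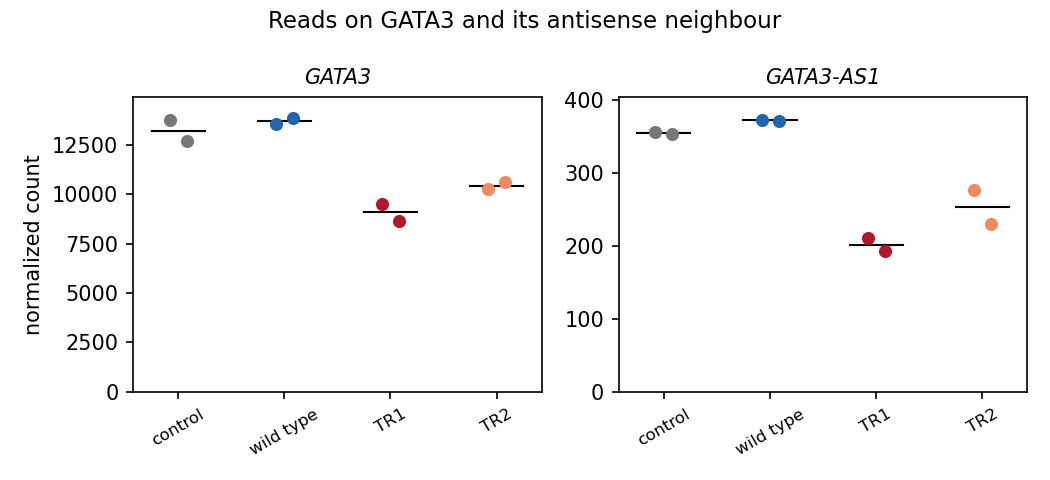
Normalized counts of GATA3 (linear axis from 0) in each of the 8 libraries, grouped by plasmid; points are libraries and bars are group means. The TR1 libraries lie at 9506 and 8638, below the control libraries at 13730 and 12680.

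Cells with the wild-type plasmid were compared with cells with the control plasmid, although GATA3 counts were not detectably raised by it (fold 1.04, 95% limits 0.935 and 1.15). MMP16, which encodes a membrane-bound matrix metalloproteinase, rose from 2.83 ± 0.55 to 147.3 ± 8.25 normalized counts (log2 fold change 5.28 ± 0.39, limma adjusted p = 0.000746). The netrin receptor gene UNC5C had 0 reads in the control and 19.07 ± 4.37 normalized counts with wild type, at least 5.54-fold higher (adjusted p = 0.0019). CLSTN2, a calsyntenin gene, rose from 9.56 ± 3.18 to 99.74 ± 0.64 (3.29 ± 0.30, adjusted p = 0.00147). In the other direction, the chemokine gene CXCL14 had 14.37 ± 2.09 in the control and 0 reads with wild type, at least 4.55-fold lower (adjusted p = 6.86e-05). GLYATL3 fell from 44.85 ± 7.24 to 5.83 ± 1.44 (-2.75, adjusted p = 0.000746), AGPAT4 from 107.2 ± 8.78 to 21.08 ± 5.61 (-2.31, adjusted p = 0.00101) and the integrin gene ITGA5 from 1091 ± 4.93 to 579.3 ± 42.6 (-0.91, adjusted p = 0.00169). These 7 genes kept their call under every alternative that tested them and with each library left out, among the 30 named genes past the threshold. CP, which encodes ceruloplasmin, fell from 71.18 ± 4.13 to 3.73 ± 1.18 (-3.95, adjusted p = 0.000845), and voom weights gave an adjusted p of 0.284.

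In total, limma called 251 genes between wild type and control, 102 higher and 149 lower with wild type, and 115 of them changed at least 2-fold. An unadjusted p under 0.05 was reached by 1968 genes. The count was 64 without control replicate 1, 73 without control replicate 2, 49 without either wild-type replicate 1 or wild-type replicate 2, 135 without TR2 replicate 1 or TR2 replicate 2, and 1758 without TR1 replicate 1 or TR1 replicate 2. The lower majority turned with only these groups (820 higher, 493 lower), without TR1 replicate 1 (1100 and 658), without TR1 replicate 2 (1085 and 673) and without control replicate 1 (34 and 30).

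Of the state markers, FN1 rose with wild type from 644.1 ± 48.9 to 1028 ± 45.3 (0.68, limma adjusted p = 0.0115). Its call was lost without control replicate 1 (adjusted p = 0.055), control replicate 2 (0.111), wild-type replicate 1 (0.102) or wild-type replicate 2 (0.149), and with the length and GC trend removed (0.201). CDH1 (0.11, adjusted p = 0.516), VIM (-0.35, 0.727), FOXA1 (-0.09, 0.603) and KRT8 (-0.05, 0.772) did not pass, nor did ESR1 (-0.26, 0.175) and PGR (0.42, 0.585), and ZEB1 had 0 reads in both groups. ESR1 and PGR passed with only these groups (adjusted p = 0.0118 and 0.00102), without TR1 replicate 1 (0.0198 and 0.000933) and without TR1 replicate 2 (0.0188 and 0.000822), and ESR1 with the trend removed (0.0419).

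Among gene lists, camera placed the estrogen response higher with wild type (adjusted p = 0.0467, and adjusted p = 0.83 with an estimated correlation). Of its 33 measured members, 4 rose, EGR3 (4.05) among them, and 1 fell, WISP2 (-1.10), with 28 not past the threshold. Adjusted over the list alone, 7 rose and 3 fell. The interferon response was placed lower (adjusted p = 0.0385, and adjusted p = 0.535 with an estimated correlation), and 1 of its 28 members, IFI6, fell from 292.9 ± 12.5 to 166.0 ± 7.28. Adjusted over the list alone, 0 rose and 3 fell. Without control replicate 1 both lists had an adjusted p of 0.0506, and without wild-type replicate 2 the estrogen response had 0.15 and the interferon response 0.0831. Without control replicate 2 the estrogen response had 0.0751. Both calls were lost with a stricter filter (adjusted p = 0.14), and that of the estrogen response under 4 other settings (adjusted p between 0.0506 and 0.152). Without control replicates 1 and 2 and wild-type replicates 1 and 2, in this order, EGR3 had adjusted p of 0.0693, 0.0646, 0.111 and 0.116, and IFI6 of 0.118, 0.0804, 0.131 and 0.0935. WISP2 had 0.116 without control replicate 1, 0.106 without wild-type replicate 1, 0.109 without wild-type replicate 2 and 0.0507 with voom weights.

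Cells with the TR1 plasmid were compared with the control next. CXCL14 (chromosome 5, 135570679 to 135579279) rose from 14.37 ± 2.09 to 2140 ± 203 normalized counts (log2 fold change 7.13 ± 0.19, limma adjusted p = 1.74e-07). DACT1, which encodes a regulator of Wnt signalling, had 1 read in the control and 168.4 ± 16.9 normalized counts with TR1, a ratio of 293 with a 95% counting interval of 52.3 to 11600. The secreted Wnt antagonist gene SFRP1 also had 1 control read and reached 115.1 ± 11.4, a ratio of 201 (35.7 to 7950). RIMS2 and STC1 had 0 control reads and were at least 19.8-fold and at least 17.2-fold higher. PMP22 had 3 control reads and reached 156.1 ± 4.07, a ratio of 91.2 (31.0 to 445). LMO4, a LIM-domain cofactor gene, rose from 1139 ± 30.1 to 3696 ± 36.9 (1.70 ± 0.06, adjusted p = 2.52e-06), and EHF, an epithelial ETS factor gene, from 245.5 ± 38.6 to 1051 ± 320 (2.07, adjusted p = 0.000453).

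The ephrin receptor gene EPHA4 (chromosome 2, 221418027 to 221574202) fell with TR1 from 932.1 ± 54.7 to 65.31 ± 3.63, 14.1-fold lower (-3.81 ± 0.10, limma adjusted p = 1.74e-07). TMTC1, which encodes a mannosyltransferase of the endoplasmic reticulum, fell from 645.6 ± 1.16 to 45.31 ± 0.998 (-3.80 ± 0.10). ADAMTS15, a secreted metalloprotease gene, fell from 194.4 ± 31.9 to 15.57 ± 2.82 (-3.56) and SLC24A3 from 400.4 ± 4.34 to 44.95 ± 0.87 (-3.13). Among immediate early genes, the phosphatase gene DUSP4 fell from 1866 ± 134 to 399.1 ± 49.8 (-2.23, adjusted p = 5.3e-06), JUN by a log2 change of -0.94 and CYR61 by -0.77. Of the 84 named genes past the threshold, 43 kept their call under every alternative that tested them and with each library left out, and these include all the genes given above for TR1 and the control.

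Limma called 1578 genes between TR1 and control, 731 higher and 847 lower, with 309 of the former and 161 of the latter at least 2-fold. The count was 604 without control replicate 1, 630 without control replicate 2, 953 and 949 without wild-type replicates 1 and 2, 998 and 1014 without TR2 replicates 1 and 2, and 5170 without TR1 replicate 1. The balance of directions was not stable, with 2970 higher and 2200 lower without TR1 replicate 1 and 278 higher and 205 lower with only these groups.

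**Figure D2:**
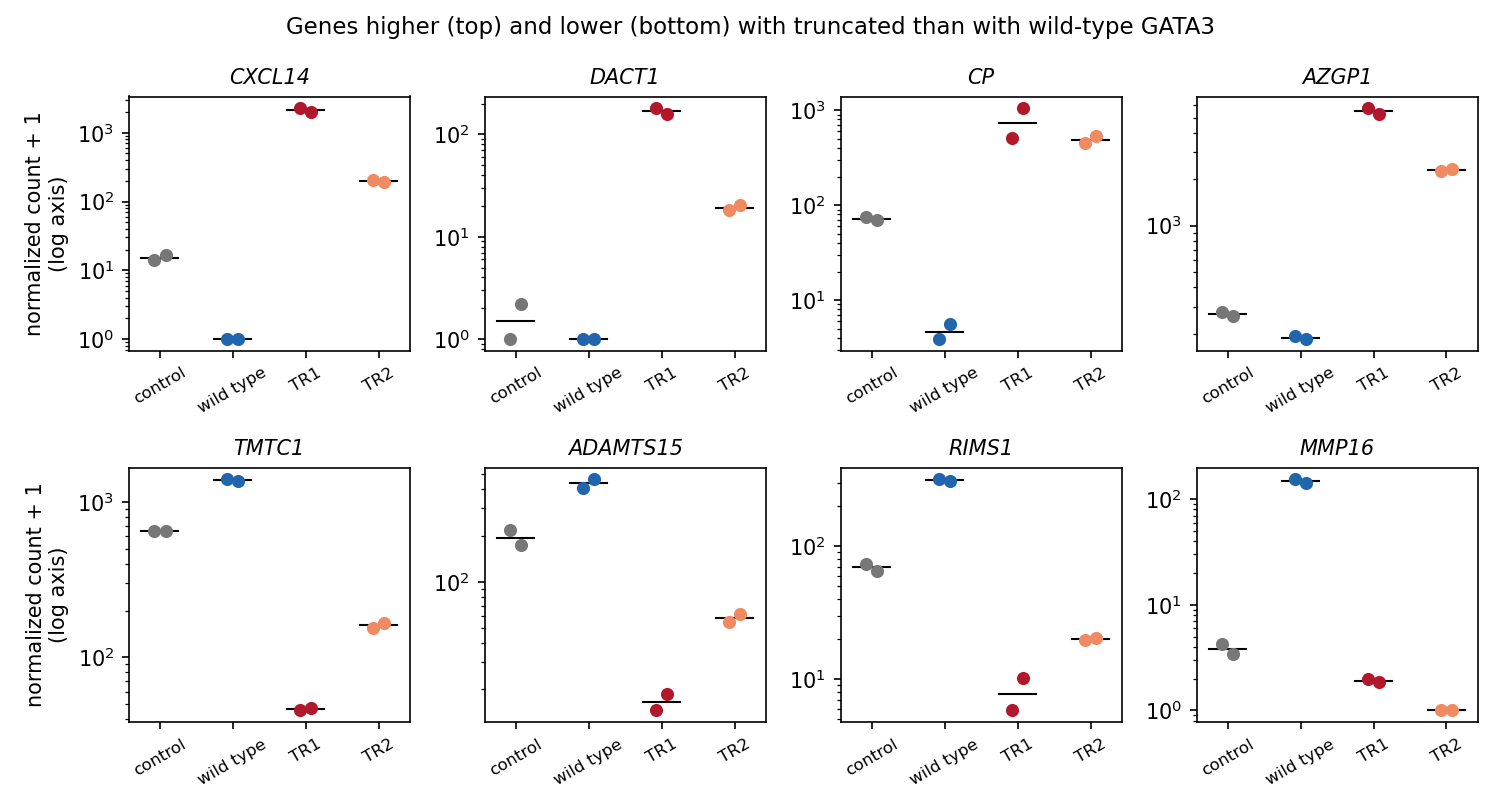
Normalized count + 1 (log axis) of CXCL14, DACT1, CP, AZGP1, TMTC1, ADAMTS15, RIMS1 and MMP16 in each library; points are libraries and bars are group means on the log scale. CXCL14 lies at 0 in both wild-type libraries, at 12.89 and 15.85 in the control, and at 2283 and 1997 with TR1.

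Genes of the mesenchymal state were measured because the study's title raises it. Of 23 measured members of that list, 7 rose with TR1 against the control and 1 fell, and adjusted over the list alone 9 rose and 2 fell. MMP2 and COL3A1 had 0 control reads and were at least 3.70-fold and at least 5.64-fold higher with TR1, at 12.71 ± 2.59 and 19.38 ± 1.38 normalized counts. SPARC had 1 control read and 20.37 ± 5.50 with TR1, a ratio of 36.2 (95% counting interval 6.18 to 1460). VIM, the vimentin gene, rose from 7.95 ± 0.90 to 40.29 ± 6.10 (2.20 ± 0.39, limma adjusted p = 0.00939), a call lost without control replicate 2 (adjusted p = 0.0647), while COL1A1 fell from 378.0 ± 1.53 to 220.3 ± 21.7 (-0.78, adjusted p = 0.00291). Camera did not place the list apart from other genes (adjusted p = 0.257), with a mean log2 fold change of 0.79 and a median of 0.05. By fry, which asks whether members move one way on balance and compares them with no other genes, the list was higher (adjusted p = 0.00113). Of 21 TGF-beta targets, 7 rose and 1 fell, and 8 and 2 did so adjusted over the list alone. Camera did not place them apart either (adjusted p = 0.253, mean 0.64, median 0.05), and by fry they were higher (adjusted p = 0.00223). They include INHBA, with 2 control reads and 46.58 ± 11 with TR1, a ratio of 41.3 (11.2 to 345). The fry calls were not particular to these lists, since fry called 8 lists here that camera did not. Luminal identity (fry adjusted p = 0.00502) and basal and myoepithelial genes (0.00113) were among them, both higher.

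The epithelial cadherin gene CDH1 was at 8176 ± 285 with TR1 and 8135 ± 515 in the control (log2 fold change 0.01, limma adjusted p = 0.947). The fibronectin gene FN1 (0.30, adjusted p = 0.0872) and the estrogen receptor gene ESR1 (0.24, adjusted p = 0.0843) did not pass the threshold, but did without TR1 replicate 2 (0.0132 and 0.0435). FOXA1, a luminal pioneer factor gene, was lower (-0.28, adjusted p = 0.0324), a call lost without control replicate 1 (0.194), control replicate 2 (0.0832), wild-type replicate 1 (0.071), wild-type replicate 2 (0.0712), TR2 replicate 1 (0.0557) or TR2 replicate 2 (0.0553), and under 4 other settings (0.0568 to 0.16). ZEB1 had 2 reads with TR1 and 0 in the control. PGR, the progesterone receptor gene, stood at 7826 and 18200 in the TR1 libraries and did not pass (0.95 ± 0.30, adjusted p = 0.0788). It passed without TR1 replicate 1 (1.56, adjusted p = 1.5e-08) and without TR1 replicate 2 (0.34, adjusted p = 0.00943), with median centring (0.86, adjusted p = 0.00806), with the replicate number as a block (adjusted p = 0.0495) and with the length and GC trend removed (0.60, adjusted p = 0.026). The keratin gene KRT8 was higher with TR1 (0.36, adjusted p = 0.01), but not without control replicate 1 (adjusted p = 0.1), with median centring (0.135), with quantile normalization (0.282), with no trend in the prior variance (0.0667) or with only these groups (0.0819).

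Of 28 interferon response genes, 9 rose with TR1 against the control and 0 fell, and 15 rose and 0 fell adjusted over the list alone. ISG15, which encodes a ubiquitin-like modifier, rose from 53.84 ± 8.91 to 135.3 ± 11.6 (1.32 ± 0.21, limma adjusted p = 0.00535). Camera placed the list higher (adjusted p = 6.65e-05, and adjusted p = 0.137 with an estimated correlation), with a median log2 fold change of 0.60. The cell cycle genes were placed lower (adjusted p = 0.00126, and adjusted p = 0.547 with an estimated correlation), with 5 of 30 past the threshold, all lower, 11 lower adjusted over the list alone, and a mean log2 fold change of -0.10. Immediate early genes were placed lower (adjusted p = 0.0124, and adjusted p = 0.547 with an estimated correlation), and 5 of 16 fell, while adjusted over the list alone 7 fell and 1 rose. Their call was lost once a length and GC trend was removed (adjusted p = 0.106).

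Progestin response genes were placed higher with TR1 (camera adjusted p = 0.0399, and adjusted p = 0.547 with an estimated correlation), with 5 of 16 members higher both over all genes and adjusted over the list alone. Their call was lost without control replicate 2 (adjusted p = 0.208) or TR1 replicate 1 (0.35), and under 4 other settings (0.0508 to 0.0617). Mitochondrially encoded genes were placed higher as well (adjusted p = 0.0319, and adjusted p = 0.727 with an estimated correlation), and 3 of 13 rose, also adjusted over the list alone. That call was lost without control replicate 2 (adjusted p = 0.288), without TR1 replicate 2 (0.192) and under 6 other settings, median centring and quantile normalization among them (0.0509 to 0.292).

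**Figure D3:**
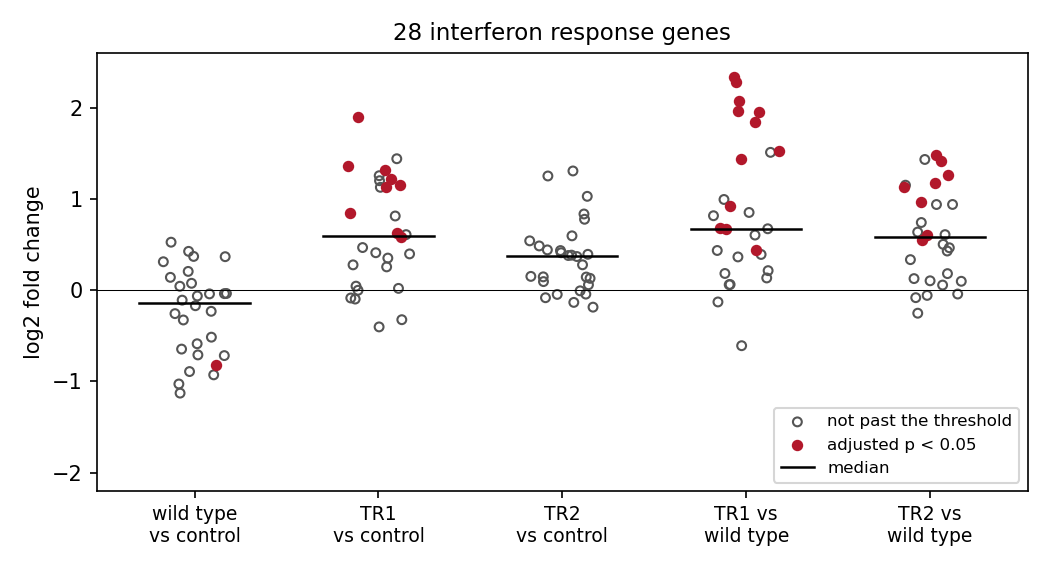
Log2 fold changes of the 28 measured interferon response genes in 5 comparisons; points are genes and the line is the median. The median is 0.60 for TR1 against the control and -0.14 for wild type against the control.

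Markers of other cell types were read in each library. The fibroblast marker DCN had 66 and 70 reads in the TR1 libraries, 3 and 2 with TR2 and 0 in the control and wild-type libraries, at least 17.8-fold higher with TR1 than in the control. LUM had 8 and 33 reads with TR1 and 0 elsewhere, whereas COL1A2 had 0 reads in all 8 libraries and COL1A1 was lower with TR1. The leukocyte genes CD14, CD68, LYZ, CD74 and LAPTM5 and the basal keratin genes KRT5 and KRT14 had at most 3 reads in any library.

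Cells with the TR2 plasmid were likewise compared with the control. AZGP1, which encodes a secreted zinc-binding glycoprotein (chromosome 7, 99966720 to 99976157), rose from 267.9 ± 9.94 to 2294 ± 34.1 normalized counts (log2 fold change 3.09 ± 0.08, limma adjusted p = 6.95e-07). CXCL14 rose from 14.37 ± 2.09 to 197.6 ± 7.83 (3.70 ± 0.19, adjusted p = 5.83e-05), the gap junction gene GJA1 from 35.39 ± 0.06 to 188.7 ± 10.1 (2.38, adjusted p = 0.000298) and LMO4 from 1139 ± 30.1 to 2360 ± 44.5 (1.05, adjusted p = 0.000183). GFRA1, which encodes a GDNF co-receptor, fell from 232.2 ± 30.1 to 43.44 ± 5.50 (-2.39, adjusted p = 0.00135) and TMTC1 from 645.6 ± 1.16 to 159.4 ± 8.10 (-2.01, adjusted p = 5.34e-05). These 6 genes, of 26 named past the threshold, kept their call under every alternative that tested them and with each library left out. VIM did not pass (17.76 ± 4.12 against 7.95 ± 0.90, adjusted p = 0.247), nor did CDH1 (-0.04, adjusted p = 0.736).

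Limma called 137 genes between TR2 and control, 78 higher and 59 lower, and 56 of them changed at least 2-fold. The share of higher genes was 56.9%, against 43.9% with median centring, which gave 111 higher and 142 lower. The majority also turned with quantile normalization (93 and 99), adjustment over all 6 comparisons (174 and 195) and the length and GC trend removed (147 and 150). The count was 2736 and 2747 without TR1 replicates 1 and 2, 31 and 36 without control replicates 1 and 2, 72 and 69 without wild-type replicates 1 and 2, and 18 without TR2 replicate 1 or TR2 replicate 2. The interferon response was placed higher by camera (adjusted p = 0.00475, and adjusted p = 0.309 with an estimated correlation). No single member passed over all genes, where 0 of 28 rose, and 1 rose adjusted over the list alone, with a median log2 fold change of 0.38. With a stricter filter the list had an adjusted p of 0.0732.

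The markers FN1 (-0.16, limma adjusted p = 0.401), ESR1 (0.10, 0.475), FOXA1 (-0.09, 0.477) and KRT8 (0.14, 0.3) did not pass between TR2 and the control, and ZEB1 had 1 read with TR2 and 0 in the control. PGR did not pass (0.66, adjusted p = 0.299), but did with only these groups (0.000172), without TR1 replicate 1 (2.25e-05) and without TR1 replicate 2 (1.75e-05).

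TR1 and wild type were compared directly, with GATA3 counts raised over the control in neither group. CXCL14 had 0 reads with wild type and 2140 ± 203 normalized counts with TR1, at least 678-fold higher (limma adjusted p = 9.18e-09). DACT1 was at least 53.3-fold and SFRP1 at least 36.5-fold higher. GLYATL3, a glycine acyltransferase family gene, was at 5.83 ± 1.44 with wild type and 481.3 ± 22.8 with TR1 (log2 fold change 6.16 ± 0.21, adjusted p = 7.16e-07). CP was at 3.73 ± 1.18 with wild type and at 504.2 and 1053 in the TR1 libraries (7.29 ± 0.32). In the other direction, TMTC1 fell from 1382 ± 24.0 to 45.31 ± 0.998, 29.9-fold lower (-4.90 ± 0.10, adjusted p = 2.48e-08), RIMS1, a presynaptic scaffold gene, from 314.2 ± 5.31 to 7.03 ± 3.08 (-5.35) and ADAMTS15 from 435.9 ± 38.8 to 15.57 ± 2.82 (-4.73). MMP16 had 2 reads with TR1 against 147.3 ± 8.25 normalized counts with wild type, a ratio of 0.00608 (95% counting interval 0.000732 to 0.0221). ESR1 was higher with TR1 (0.50, adjusted p = 0.00319), as were VIM (2.55, adjusted p = 0.00316) and KRT8 (0.41, adjusted p = 0.00383).

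In total 2229 genes were called between TR1 and wild type, 1131 higher and 1098 lower with TR1, and 663 changed at least 2-fold. The count was 927 and 859 without wild-type replicates 1 and 2 and 4754 without TR1 replicate 1, where 2759 were higher and 1995 lower. The balance turned with quantile normalization (973 higher, 1202 lower) and with a stricter filter (826 and 953). It also turned with voom weights (1103 and 1117), with the length and GC trend removed (1316 and 1419) and without TR1 replicate 2. Of 90 named genes past the threshold, 60 kept their call under every alternative that tested them and with each library left out, among them all those given above for TR1 and wild type. Of 28 interferon response genes 12 rose, or 17 adjusted over the list alone, and 0 fell, with OASL (2.29), IFIT1 (2.07) and ISG15 (1.97) among them. Camera placed this list higher (adjusted p = 1e-07, and adjusted p = 0.0598 with an estimated correlation). Immediate early genes were placed lower (adjusted p = 0.00103, and adjusted p = 0.416 with an estimated correlation), with 7 of 16 lower, DUSP4 (-2.46) and JUN (-0.86) among them, and the same number adjusted over the list alone.

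Cell cycle genes were also placed lower with TR1 than with wild type (camera adjusted p = 0.00184, and adjusted p = 0.574 with an estimated correlation), with 4 of 30 lower over all genes and adjusted over the list alone. Unfolded protein and amino acid stress genes were placed higher (adjusted p = 0.0423, and adjusted p = 0.596 with an estimated correlation), and 7 of 20 rose and 1 fell, also adjusted over the list alone. Their call was lost without wild-type replicate 2 (adjusted p = 0.0508) or TR1 replicate 1 (0.305), and under 3 other settings (0.0567 to 0.0769). DDIT4, a stress-induced regulator of mTOR, rose from 640.2 ± 66.2 to 1786 ± 133 (1.48, adjusted p = 3.67e-05). Mitochondrially encoded genes were placed higher (adjusted p = 0.0477, and adjusted p = 0.753 with an estimated correlation), with 3 of 13 higher over all genes and adjusted over the list alone, and the call was lost without wild-type replicate 1 (adjusted p = 0.136) or TR1 replicate 2 (0.189), and under 7 other settings (0.0531 to 0.664). Mesenchymal genes did not pass (camera adjusted p = 0.0512, fry adjusted p = 0.000924), although 9 of 23 rose and 3 fell over all genes and adjusted over the list alone. Fry called 9 lists here that camera did not, luminal identity (fry adjusted p = 0.00593) and basal and myoepithelial genes (0.0011) among them.

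Markers of other cell types moved between TR1 and wild type as well, though camera did not place the fibroblast (adjusted p = 0.422), triple-negative basal (0.481) or endothelial (0.263) lists apart. Of 4 fibroblast markers 2 rose, DCN (at least 19.4-fold) and COL3A1 (at least 6.14-fold), and COL1A1 fell (-0.89). Of 6 markers of triple-negative basal lines 3 rose, VIM, MSN (0.82, limma adjusted p = 0.00818) and EGFR (0.43, 0.0397), and CD44 fell (-0.48, 0.00304). The only endothelial marker tested, ESAM, was higher with TR1 (0.69, 0.0225) and with TR2 (0.85, 0.0191) than with wild type. Without wild-type replicates 1 and 2, MSN had 0.0546 and 0.068, EGFR 0.211 and 0.157, and ESAM 0.0546 and 0.168 with TR1 and 0.065 and 0.172 with TR2. EGFR was also lost without TR2 replicate 1 (0.0699) or TR2 replicate 2 (0.0694) and under 5 other settings (0.0523 to 0.0987), MSN and ESAM with TR1 with only these groups (0.0509 and 0.104), and ESAM with TR2 without TR2 replicate 1 (0.175) or TR2 replicate 2 (0.115).

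Of the state markers, FN1 was lower with TR1 than with wild type (-0.38, limma adjusted p = 0.0314). This call was lost without wild-type replicate 1 (0.118), wild-type replicate 2 (0.222), TR2 replicate 1 (0.0661) or TR2 replicate 2 (0.0659), and under 6 other settings (0.0511 to 0.108). CDH1 (-0.10, adjusted p = 0.356), FOXA1 (-0.19, 0.0956) and PGR (0.53, 0.297) did not pass, and ZEB1 had 2 reads with TR1 and 0 with wild type. Without TR1 replicate 1, FOXA1 (0.021) and PGR (1.99e-07) passed.

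TR2 was compared with wild type in the same way. CXCL14 was at least 62.6-fold higher with TR2 (limma adjusted p = 2.28e-07), CP was at 491.5 ± 56.9 against 3.73 ± 1.18 (log2 fold change 6.72 ± 0.32), and GLYATL3 at 126.2 ± 13.2 against 5.83 ± 1.44 (4.23 ± 0.21). MMP16 had 0 reads with TR2, at least 53.8-fold lower than with wild type. RIMS1 fell from 314.2 ± 5.31 to 19.18 ± 0.43 (15.6-fold lower, adjusted p = 0.000104) and GFRA1 from 433.1 ± 34.8 to 43.44 ± 5.50 (-3.29). ITGA5 was higher (0.89) and FN1 lower (-0.83, adjusted p = 0.00163). Of the 65 named genes past the threshold, 31 kept their call under every alternative that tested them and with each library left out, and these include the 8 genes given here.

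Limma called 780 genes between TR2 and wild type, 409 higher and 371 lower, and 277 changed at least 2-fold. The count was 240 and 252 without wild-type replicates 1 and 2, 226 and 251 without TR2 replicates 1 and 2, and 2093 and 2114 without TR1 replicates 1 and 2. The higher majority turned with voom weights (353 higher, 385 lower), a stricter filter (315 and 325) and the length and GC trend removed (544 and 552). It also turned without TR2 replicate 2. Of 28 interferon response genes 8 rose, or 12 adjusted over the list alone, and 0 fell. IFI6 reached 445.0 ± 59.7 against 166.0 ± 7.28 with wild type (1.41, adjusted p = 0.000294). Camera placed the list higher (adjusted p = 5.63e-07, and adjusted p = 0.0723 with an estimated correlation). Immediate early genes were placed lower (adjusted p = 0.0143, and adjusted p = 0.635 with an estimated correlation), with 5 of 16 lower, while adjusted over the list alone 6 fell and 2 rose, and the call was lost without wild-type replicate 2 (adjusted p = 0.0753).

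ESR1 was higher with TR2 than with wild type (0.36, limma adjusted p = 0.0286). Its call was lost without control replicate 1 (0.0568), control replicate 2 (0.0566), wild-type replicate 1 (0.195), wild-type replicate 2 (0.211) or TR2 replicate 2 (0.215), and under 4 other settings (0.054 to 0.111). CDH1 (-0.16, adjusted p = 0.245), VIM (1.40, 0.0861), KRT8 (0.19, 0.157), PGR (0.24, 0.745) and FOXA1 (0.987) did not pass, and ZEB1 had 1 read with TR2 and 0 with wild type. VIM, KRT8 and PGR passed with only these groups (0.0176, 0.0131 and 0.00184), without TR1 replicate 1 (0.0396, 0.0291 and 0.0189) and without TR1 replicate 2 (0.0362, 0.0272 and 0.0179), and CDH1 with only these groups (0.0295).

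TR2 was last compared with TR1. EPHA4 was at 368.5 ± 5.05 normalized counts with TR2 and 65.31 ± 3.63 with TR1 (log2 fold change 2.48 ± 0.10, limma adjusted p = 2.41e-05). LIN28A, which encodes an RNA-binding regulator of let-7, was at 235.4 ± 20.5 against 51.04 ± 14.2 (2.21, adjusted p = 0.000611), and TMTC1 (1.79) and DUSP4 (1.33) were also higher with TR2. The smooth muscle actin gene ACTA2 was lower with TR2, at 998.4 ± 61.5 against 3171 ± 241 (-1.67 ± 0.09, adjusted p = 0.000114), as were TRIM29 (-1.20) and the thrombospondin gene THBS1 (-0.72). These 7 genes, of 28 named past the threshold, kept their call under every alternative that tested them and with each library left out. VIM did not pass (-1.15, adjusted p = 0.315).

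Between TR2 and TR1, GATA3 (0.20, limma adjusted p = 0.295), CDH1 (-0.05, 0.912), ESR1 (-0.13, 0.66), FOXA1 (0.19, 0.344), KRT8 (-0.22, 0.229) and FN1 (-0.45, 0.0741) did not pass, and ZEB1 had 1 read with TR2 and 2 with TR1. GATA3 passed without TR1 replicate 1 (0.0132) and KRT8 without TR1 replicate 2 (0.0166). FN1 passed without TR1 replicate 1 (0.0273), without TR1 replicate 2 (0.00269), with robust empirical Bayes (0.0474) and with adjustment over all 6 comparisons (0.0314). PGR did not pass (-0.29, 0.883), and was lower without TR1 replicate 1 (-0.90, adjusted p = 2.22e-05) and higher without TR1 replicate 2 (0.32, adjusted p = 0.0185).

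Limma called 181 genes between TR2 and TR1, 87 higher and 94 lower with TR2, and 75 changed at least 2-fold. The count was 1577 and 1260 without TR1 replicates 1 and 2, 30 and 29 without TR2 replicates 1 and 2, and 107 and 106 without wild-type replicates 1 and 2. The balance of directions was not stable, with 405 higher and 1172 lower without TR1 replicate 1, 890 and 370 without TR1 replicate 2, and 11 and 48 with only these groups. Camera placed mesenchymal genes lower with TR2 (adjusted p = 0.00269, and adjusted p = 0.302 with an estimated correlation), with 1 of 23 lower and 6 lower adjusted over the list alone. TGF-beta targets were placed lower (adjusted p = 0.0107, and adjusted p = 0.302 with an estimated correlation), with 1 of 21 lower, and 6 lower and 1 higher adjusted over the list alone. The interferon response was placed lower (adjusted p = 0.00257, and adjusted p = 0.302 with an estimated correlation), with 1 of 28 lower and 3 adjusted over the list alone. Without TR1 replicate 1 these 3 lists had adjusted p of 0.227, 0.173 and 0.0522, and without TR1 replicate 2 the TGF-beta targets had 0.124. With a stricter filter the mesenchymal genes had 0.65 and the TGF-beta targets 0.333.

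Other lists were placed apart between TR2 and TR1 with at most 1 member past the threshold. Cell cycle genes were placed higher with TR2 (camera adjusted p = 0.000116, and adjusted p = 0.361 with an estimated correlation), with 0 of 30 past the threshold over all genes or adjusted over the list alone. Immediate early genes were placed higher (adjusted p = 0.00329, and adjusted p = 0.302 with an estimated correlation), with 1 of 16 higher and 2 adjusted over the list alone, and not without TR1 replicate 2 (adjusted p = 0.124). Progestin response genes were placed lower (adjusted p = 0.0237, and adjusted p = 0.395 with an estimated correlation), with 0 of 16 past the threshold and 1 lower adjusted over the list alone, and not without TR1 replicate 1 (adjusted p = 0.455) or TR2 replicate 1 (0.0823), or with a stricter filter (0.074). The 4 measured fibroblast markers were placed lower (adjusted p = 0.0107, and adjusted p = 0.395 with an estimated correlation), with 1 lower, and 3 lower and 1 higher adjusted over the list alone, and not without TR1 replicate 1 (adjusted p = 0.505) or TR1 replicate 2 (0.115), or with a stricter filter (0.209). Ribosomal proteins were placed higher (adjusted p = 0.0107, and adjusted p = 0.832 with an estimated correlation), with 0 of 26 past the threshold and 0 adjusted over the list alone, and not without TR1 replicate 2 (adjusted p = 0.861) or TR2 replicate 1 (0.766), or under 3 other settings (0.0589 to 0.0942).

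Fold changes of the truncated variants against the control were correlated across 14881 genes, with Pearson's r of 0.791 and Spearman's rho of 0.786. Unchanged groups that share a control gave a simulated r of 0.498 ± 0.012 (SD over 100 simulations). The covariance was 0.155, against a simulated 0.0242. Between these variants 78 genes were called higher in both, where independent lists would share 3.83, and 56 lower in both, against 3.36, with 0 in opposite directions. Of the 2229 genes called between TR1 and wild type, 1919 (86.1%) had the same sign between TR2 and the control, a comparison that shares no library with the former. Without TR1 replicate 2, r was 0.637. Measured against wild type, whose libraries both comparisons share, r was 0.847 and rho 0.779, beside the r of 0.498 simulated for unchanged groups, and the covariance was 0.224, beside the simulated 0.0242, with 388 genes higher in both, 343 lower in both and 2 opposite. Here independent lists would share 31.1 and 27.4.

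Wild type and TR1 against the control had a Pearson's r of 0.134 (Spearman's rho 0.312) and a covariance of 0.0262, beside the simulated 0.0242. The simulated value does not follow the spread of the control pair itself. It therefore does not show how much of this covariance came from shared control values. They shared 25 genes called higher in both (independent lists would share 5.01) and 25 lower in both (8.48). Another 79 genes went in opposite directions, 32 of them higher with wild type (5.81) and 47 lower (7.32). With control replicate 1 or 2 left out, 20 and 24 were opposite and 14 and 18 the same, without wild-type replicate 1 or 2, 19 and 19 against 8 and 13, and without TR2 replicate 1 or TR2 replicate 2, 43 against 28. Without TR1 replicate 1 the majority turned, with 233 opposite and 947 the same, and without TR1 replicate 2 it was 261 and 197. This r was 0.00212 without TR1 replicate 2, 0.223 without TR1 replicate 1, 0.247 without control replicate 1 and 0.229 without control replicate 2. Wild type and TR2 had r of 0.293 (rho 0.412, covariance 0.0394), with 10 genes higher in both (0.535), 6 lower in both (0.591) and 28 opposite. Without TR1 replicate 1 this was 148 opposite and 789 the same way, without TR1 replicate 2 it was 154 and 779, and with only the groups compared 111 and 531. It was 3 and 4 without control replicate 1, 4 and 5 without control replicate 2, 10 and 3 without wild-type replicate 1 or wild-type replicate 2, and 5 and 3 without TR2 replicate 1 or TR2 replicate 2. Each pair shares a group of 2 libraries that could not be split, and the part of the shared calls due to it was not separated.

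**Figure D4:**
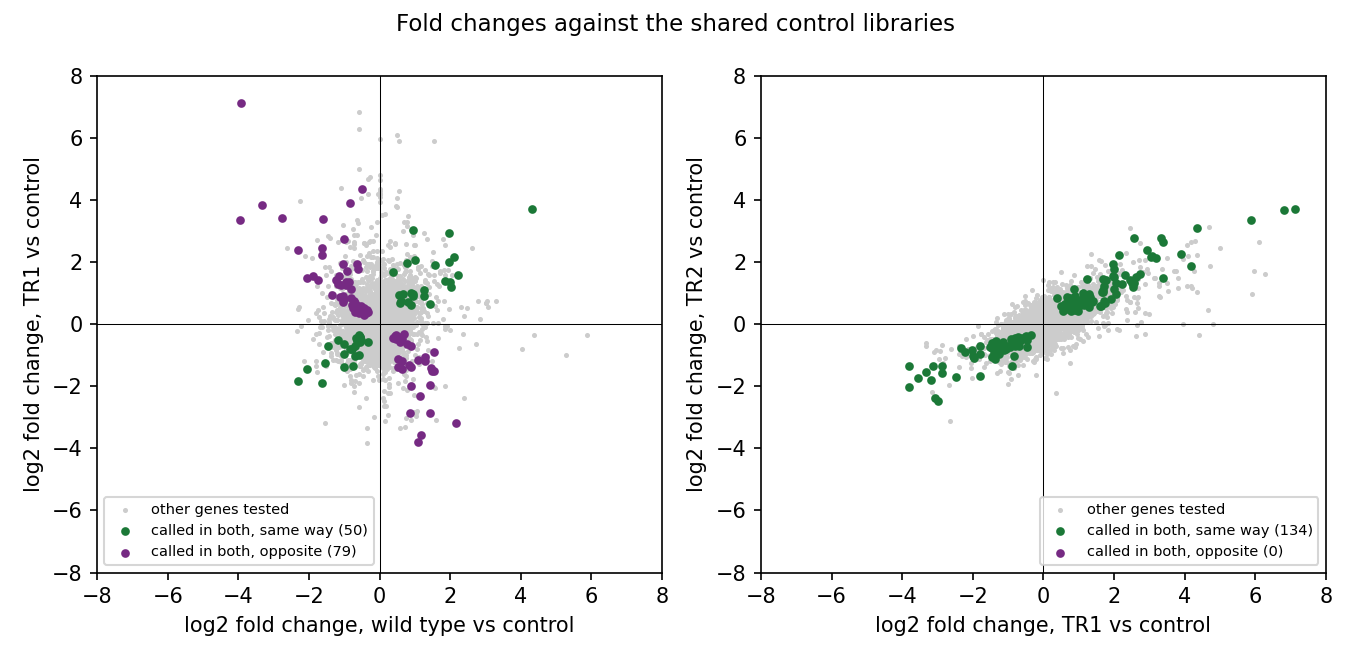
Log2 fold changes of each gene against the control, wild type against TR1 on the left and TR1 against TR2 on the right; coloured points are genes called in both. On the left 50 genes share a direction and 79 do not, and on the right 134 share a direction and 0 do not.

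The remaining lists were placed apart by camera in none of the 6 comparisons, except the estrogen response with wild type. For TR1 against the control, 5 of 23 luminal identity genes rose and 4 fell, with EHF (2.07), ELF3 (0.77) and SPDEF (-0.59) among them, and adjusted over the list alone 7 rose and 4 fell. Of 31 epithelial junction genes 3 rose and 2 fell, and adjusted over the list alone 3 rose and 3 fell. Of 23 sterol and fatty acid synthesis genes 5 rose and 2 fell, with FADS1 (0.55) and FDFT1 (-0.49) among them, and adjusted over the list alone 7 rose and 3 fell. Of 21 receptor tyrosine kinases and ligands 3 rose and 5 fell, with AREG (-1.13) among them, and adjusted over the list alone 4 rose and 5 fell. Camera's direction for this list was lower while its mean was 0.09 and its median -0.04. Of 11 basal and myoepithelial genes 3 rose, TRIM29 (1.60) and LAMB3 (1.30) among them, and 1 fell, and adjusted over the list alone 5 rose and 2 fell. Of 33 estrogen response genes 9 rose and 8 fell with TR1, and adjusted over the list alone 14 rose and 10 fell. Of 20 cell motility and integrin genes 2 rose and 4 fell, or 3 and 5 adjusted over the list alone, and camera's direction was lower (adjusted p = 0.897) while the mean was 0.23 and the median 0.16. Of 21 hypoxia and glycolysis genes 1 rose and 2 fell, and of 8 GATA family and cofactor genes 1 rose and 1 fell. Of the 6 measured markers of triple-negative basal lines 1 rose, VIM, and 1 fell, CD44 (-0.47, adjusted p = 0.0046, or 0.0636 with only these groups).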

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

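Of the tests weighed in this part, the sequencing depth tests, the trend test of the opposite genes and the position over 1260 genes were planned before the result was seen, and all others were chosen after it.

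The effects of wild-type GATA3 and of a truncated variant against the control were called in opposite directions, with the difference between them also called, for 79 genes with TR1 and 28 with TR2. With 1 control or wild-type library left out, 19 to 24 genes were opposite with TR1. By the naming rule 18 and 10 of these are given, as the log2 difference of the variant from wild type. For TR1 the difference was 11.06 at CXCL14, 7.29 at CP, 7.15 at MXRA5, 6.16 at GLYATL3, 5.01 at PLEKHS1, 4.87 at AZGP1, 4.70 at GAD1, 2.35 at WISP2, 1.95 at IFI6, 1.37 at FGFR2 and 1.37 at PMEPA1. It was -5.35 at RIMS1, -4.90 at TMTC1, -4.73 at ADAMTS15, -3.73 at HSPB8, -1.88 at L1CAM, -1.65 at AREG and -0.998 at OLFM1. For TR2 it was 7.63 at CXCL14, 6.72 at CP, 4.27 at PLEKHS1, 4.23 at GLYATL3, 3.60 at AZGP1, -3.96 at RIMS1, -3.11 at TMTC1, -2.91 at ADAMTS15, -2.42 at HSPB8 and -1.37 at AREG. Being called opposite held under every alternative that tested it, and with each library left out, for CXCL14, GLYATL3 and TMTC1 of the 18 genes with TR1, and for CXCL14 and TMTC1 of the 10 with TR2. For CP and MXRA5 with TR1 it was lost only with voom weights, and for the other 13 and 8 genes it was lost with at least 1 library left out, up to 13 settings for GAD1 and OLFM1. The differences from wild type printed here have their own test, but opposite calls in the same fit imply that it passes. The sizes at genes with 0 reads in a group, such as CXCL14, depend on the count of 1 added before the log.

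For the opposite calls of wild type and TR1, chance values of the shared control would push unchanged genes the same way. Of the shared calls, 79 went opposite and 50 the same way, but without TR1 replicate 1 the majority turned. The test cannot decide on chance in the control, since a control value falling by chance between differing groups also gives opposite calls. The difference between TR1 and wild type was itself called at all 79 genes, and its fold changes use no control values. This outcome was fixed, because at opposite genes the difference adds the sizes of both changes, with the same SE in this fit. It therefore says nothing on chance in the control. Once a length and GC trend was removed, 72 of 75 annotated opposite genes kept both calls, and 125 genes in all were then opposite. After thinning to the shallowest library 63 of 79 kept both calls and 79 kept opposite signs. Of the 79 genes, 77 moved in the TR1 direction with TR2 as well (95% binomial limits 91.2% and 99.7%), but so did 97.1% of the other genes called for TR1. These limits treat genes as independent, which they are not, and both changes share the control libraries. Even 79 of 79 genes would have left the lower limit under 97.1%, so the test could not have favoured truncated variants that act against wild-type GATA3. Whether they do is left open.

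The TR1 libraries differ more than other pairs of replicates. Each correlated better with both TR2 libraries (Pearson's r from 0.98636 to 0.98795) than with the other TR1 library (0.98589). The SD of the log2 difference between the TR1 libraries was 0.3859. A length and GC trend took up 58.2% of the variance of this difference. With the trend removed the SD was 0.2495, where the other pairs had 0.1175 to 0.1637. After thinning to 13292861 reads it was 0.3897 (others 0.131 to 0.1745). The trend thus accounts for part of the difference but not all of it, and thinning did not lower it. Within the other pairs the trend took up 5.9% to 24.3% of the variance. It differed between groups too. The slope of log2 values per 10 points of GC was 0.0905 and 0.125 in the control libraries and -0.0182 and -0.0764 in the TR2 libraries. As to a TR2 library under a TR1 label, the planned test placed TR1 replicate 2 at a median of 1.12 (quartiles 0.318 to 1.89) on the way from TR1 replicate 1 (0) to the TR2 mean (1) over 1260 genes, and over 34 genes at least 4-fold apart, chosen afterwards, at 0.0589 (quartiles 0.00293 to 0.553), and neither decides. All these genes were ones called between TR1 replicate 1 and TR2 with TR1 replicate 2 left out. They were thus picked on extreme values of TR1 replicate 1, which moves any other library away from 0. A criterion set after both outcomes counted 24 of the 34 genes nearer to TR1 replicate 1. It counted 0 for each TR2 library, which is close to fixed because those libraries make up the TR2 mean. A last test found 39 genes at which TR1 replicate 2 lay at least 4-fold from both TR2 libraries in the same direction. The other pairs had 11 to 22, so 39 fell short of the 3 times set for it. Those pairs needed a 4-fold distance from 1 library only, an easier rule, so the counts are not alike. The count of 24 and single genes chosen after their values were seen argue against the wrong label, with CXCL14 at 1997 against 203.2 and 192.1 with TR2, DACT1 at 156.4 against 17.08 and 19.49, and DCN at 70 reads against 3 and 2, while a mixed library and biological explanations were not tested.

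For the lower GATA3 counts with TR1, quantile normalization gave -0.491 (adjusted p = 0.00028), median centring -0.634 (0.00084) and removal of the length and GC trend -0.505 (SE 0.064, 0.00057), so neither scaling nor the trend accounts for it. The antisense gene GATA3-AS1, chosen after its values were seen, was lower as well (-0.813, SE 0.12, adjusted p = 0.0032). It could reflect lower transcription at the locus, but it lies inside GATA3 and the strand setting of the counting is not stated, so the test does not decide. The fold of GATA3 with wild type over the control was 1.04 (95% limits 0.935 and 1.15), which leaves room for some reads from the introduced gene. Whether endogenous GATA3 fell further than the counts show could not be read from these values.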

How the results depend on the processing

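Removing the length and GC trend and limiting the fit to annotated genes were chosen after seeing the data. Of 6699 values of 323 called gene results under the alternatives, 5811 kept their call and 887 lost it. Of 529 values of 23 called lists, 440 kept the call and 87 lost it, among them all 23 with an estimated correlation (lowest adjusted p = 0.0598). These counts include fry, which tests another question than camera and called 8, 4 and 2 further lists for TR1 against the control, TR2 against the control and TR2 against TR1, and 9 and 7 for TR1 and TR2 against wild type. The stricter filter tested only 20 of 30, 61 of 84 and 22 of 26 named genes called for wild type, TR1 and TR2 against the control, 65 of 90 and 52 of 65 for TR1 and TR2 against wild type, and 19 of 28 for TR2 against TR1.

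Counts of changed genes moved by over 1.5 times as follows. With no trend in the prior variance TR2 against TR1 had 114, and with no filter TR2 against the control 91. Median centring gave 253 for TR2 against the control. With only the groups compared, and so fewer samples, wild type against the control had 1313, TR1 and TR2 against the control 483 and 2115, TR1 and TR2 against wild type 1042 and 2971, and TR2 against TR1 59. Adjustment over all 6 comparisons, which shares 1 threshold among them, gave 419 for wild type and 369 for TR2 against the control, and 332 for TR2 against TR1. With the length and GC trend removed, TR2 had 297 against the control and 300 against TR1.

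Leaving out 1 library gave 49 to 1758 genes for wild type against the control, 604 to 5170 for TR1 against the control, 18 to 2747 for TR2 against the control, 859 to 4754 for TR1 against wild type, 226 to 2114 for TR2 against wild type and 29 to 1577 for TR2 against TR1. The correlation of fold changes lay between 0.00212 and 0.247 for wild type and TR1, 0.257 and 0.424 for wild type and TR2, 0.637 and 0.815 for the truncated variants against the control, and 0.78 and 0.857 for them against wild type. In the same order it was 0.336, 0.439, 0.635 and 0.683 with no filter. A stricter filter gave 0.876 against the control and 0.912 against wild type, and removing the trend gave 0.00801 for wild type and TR1 and 0.143 for wild type and TR2.

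Signs turned in few results that were called in the main fit or in the alternative. Another 14 values of named genes, called in neither, changed sign too. For TR1 against wild type, quantile normalization turned MT-ND2 to -0.057 and the mean of the ribosomal proteins to -0.042. For TR2 against TR1, PGR ranged from -0.90 to 0.32 and the ribosomal protein mean from -0.00445 to 0.10 with 1 library left out, and the fibroblast marker mean was 0.28 with a stricter filter. For cell motility and integrins fry gave directions opposite to camera, with means of 0.232 and 0.138 for TR1 against the control and wild type and -0.206 for TR2 against TR1 (fry adjusted p = 0.00677, 0.0169 and 0.00926, where camera called none). In comparisons without TR1, leaving out a TR1 library changed the estimate of the spread and not the fold changes, so their counts rose through the spread. Apart from this and from the fits with fewer samples or another adjustment, the cause was not tested.

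The libraries share only a number, and correlations of same-number deviations between groups lay between -0.0898 and 0.148. With the replicate number as a block, the counts were 184, 1248 and 99 for wild type, TR1 and TR2 against the control, 1780 and 612 for TR1 and TR2 against wild type, and 125 for TR2 against TR1. With 2 libraries per group, each call rests on a spread pooled over groups that differ in it. The counts of called genes therefore do not rank the comparisons by effect. Against the control, TR1 had 1578 and TR2 137 in the main fit, and 483 and 2115 with only the groups compared.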

Other observations

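All lists and genes in this part were chosen after the gene values had been seen. The adjusted p-values of the lists cover only the 5 lists written then, and not the 22 fixed before. Retinoid targets and handling genes (14 measured) were placed higher with TR1 than in the control (camera adjusted p = 0.00461, and adjusted p = 0.278 with an estimated correlation), where 7 rose and 1 fell, and higher with TR2 than in the control (adjusted p = 0.0116, and adjusted p = 0.299 with an estimated correlation), where 3 rose and 1 fell. RARB, a retinoic acid receptor gene, was counted at 15.03 and 10.97 in the control, 5.78 and 5.71 with wild type, 123.1 and 129.7 with TR1 and 58.43 and 62.17 with TR2. CYP26A1, which encodes a retinoic acid hydroxylase, was counted at 46.54 and 42.66 with TR1, 12.58 and 16.70 with TR2 and at most 2.148 in any control or wild-type library. HLA class I and antigen presentation genes (15 measured) were placed higher with TR1 (adjusted p = 0.00189, and adjusted p = 0.278 with an estimated correlation), where 2 rose and 0 fell, and with TR2 (adjusted p = 0.0445, and adjusted p = 0.38 with an estimated correlation), where 0 rose, and reads shared between these paralogs were not resolved. Against wild type, retinoid genes were placed higher with TR1 (adjusted p = 0.00114, and adjusted p = 0.169 with an estimated correlation) and TR2 (adjusted p = 0.000565, and adjusted p = 0.283 with an estimated correlation), as were HLA genes with TR1 (adjusted p = 0.000132, and adjusted p = 0.169 with an estimated correlation) and TR2 (adjusted p = 0.00708, and adjusted p = 0.283 with an estimated correlation). Between TR2 and TR1 both lists were placed lower with TR2 (adjusted p = 0.0152 and 0.00138, and adjusted p = 0.288 with an estimated correlation for each).

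For TR1 against the control, camera placed the 17 measured collagens lower (adjusted p = 0.0433, and adjusted p = 0.364 with an estimated correlation), with 2 higher and 7 lower, a mean of 0.09 and a median of -0.20. The 15 measured ionotropic and voltage-gated channel genes were placed lower (adjusted p = 0.0411, and adjusted p = 0.278 with an estimated correlation), with 3 higher and 6 lower. For TR2 against the control, collagens (adjusted p = 0.0117) and channels (adjusted p = 0.0319) were placed lower, each with adjusted p = 0.299 with an estimated correlation, with 1 collagen and 0 channels past the threshold. The 8 measured Wnt pathway antagonists were not placed apart for TR1 against the control (adjusted p = 0.66), with 2 higher and 1 lower, and were placed higher for TR1 against wild type (adjusted p = 0.0315, and adjusted p = 0.169 with an estimated correlation), with 3 higher and 1 lower.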
